A study of Homo sapiens with 4 samples.

How the data were processed

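The data are nuclear RNA sequencing of HEC-1-A cells in 2 control libraries and 2 libraries labelled METTL3 knockdown. Per the labels' protocols, plates were seeded to hold equal numbers of cells, the nuclear fraction was separated, total RNA was purified, ERCC spike-in RNA was added in a fixed volume per sample before ribosomal RNA was depleted, and libraries were made with a stranded total RNA kit. Whether all of the RNA of a plate or a fixed mass of it entered the libraries is not given in the sources used here.

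Per the submitters' processing notes, CASAVA, Trimmomatic 0.38, HISAT2 2.1.0 and HTSeq were used with genome build hg38. The version of HTSeq, its strand setting and its annotation are not given in the sources used here. The authors deposited unnormalised read counts per gene, in a table per library and in a table of the whole series, and the series table differed from the library tables in 0 values. All 58721 gene identifiers matched GENCODE release 29, which supplied symbols, classes and coordinates. The tables also hold 92 spike-in transcripts, of which 64 were detected, and 5 summary lines of the counter, which were kept out of library sizes and tests. Of all reported reads, 47.8% lay in no annotated exon in the controls and 54.8% in the libraries labelled METTL3 knockdown, 2.51% and 1.84% were ambiguous between genes, and 4.50% and 4.43% were not uniquely aligned. Reads in introns and in ambiguous regions are therefore missing from the gene counts, and genes that share exons with a neighbour on their own strand (among those named L1CAM, GAS6-AS1, MIR100HG, ADIRF-AS1, KMT2A, BRD2, RPL13A, HSPA8, MT-CO3, MALAT1 and NEAT1) are uncertain.

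Whether counting used strand was checked on pseudogenes within introns of expressed hosts with at least 4000 counts. Processed pseudogenes on the strand of the host had a median of 140 counts over the 4 libraries (335 genes) and those on the opposite strand 4 counts (790 genes), so the counts follow strand and antisense neighbours are told apart. Replicates were compared before they were averaged. The chi-square per degree of freedom between their gene counts was 4.75 for the controls and 3.66 for the labelled knockdown libraries, against 2.77 and 2.44 for spike-ins, which no cell makes. Between groups it was 54.3 or more for genes and 3.48 to 4.99 for spike-ins. The spike-ins thus also differed somewhat more between groups than within them, which limits the spike-in scaling. On the median over features, as a ratio to the median expected from counting, genes had 3.61 and 3.34 and spike-ins 2.85 and 3.36, so that the labelled knockdown replicates differed no more in genes than in spike-ins on this measure. The replicates thus differed by more than counting noise, without a clear excess over technical noise, and each was counted as a sample.

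Gene counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM scaling, filterByExpr (22029 genes kept), a quasi-likelihood fit of the 4 libraries with group as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. The common biological coefficient of variation was 5.57%. Lists of genes and annotation classes of at least 20 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with adjustment over the 26 lists and over the 18 classes, and again with an estimated correlation. The estimates lay below 0.01 for some lists, such as ribosomal protein genes (-0.0085), and above it for others, such as G2/M genes (0.22). For ribosomal protein genes camera's p still rose from 2.5e-88 to 0.0014, so a call lost with the estimate need not mean correlated genes. A call per gene within a list was counted over all genes tested and adjusted over the list alone. Measures of a whole library were compared with a two-sided exact permutation test. On counts simulated for this comparison, with 100 genes changed 1.5-fold and 100 changed 2-fold among 21211 tested, the fit recovered 68% of the 1.5-fold and 77% of the 2-fold changes, and 5 of its 150 calls were false (3.33%). The simulated changes were few and balanced in direction, whereas 32.9% of genes passed in the data. The simulation therefore does not test the scaling or the share of false calls in the data.

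The main tests, alternatives, lists and naming rule were fixed before the data were examined. Genes were named if they were METTL3, if they passed the test with a mean of at least 5 CPM and libraries of the groups that did not overlap, taking the 10 protein-coding genes with the largest rise and the 10 with the largest fall and 3 noncoding genes each way with an official symbol, or if they were among the 4 smallest p-values of a list, and 2 genes that this rule picks were left out of the text. Where 5 or fewer members of a list moved in a direction, the others of them were named after their values had been seen. Membership of a list rests on general knowledge, and SESN2, CDH2, CD24 and a few other genes stand in more than 1 place.

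Alternatives were DESeq2 1.42.0, limma-voom, median-of-ratios factors, spike-in totals as library sizes, library size alone, no filter and a stricter filter of 1 CPM in 2 libraries, another threshold, a replicate block, leaving out each library, and leaving out mitochondrial, rRNA, 7SK and 7SL genes. For lists and classes fry was a further alternative. Follow-up tests used Python 3.11.15 and numpy 2.4.6. They compared the medians of lists with 1000 draws of genes matched, out of the 30 nearest, on expression, exonic length, GC content and intronic length, and looked at windows of 50 neighbouring protein-coding genes with a mean of at least 5 CPM. Depths between 28296403 and 43989871 gene counts per library leave counting error small for genes above a few CPM. With 2 libraries per group the spread is estimated with the help of all genes. Reads and alignments were not used here.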

Results

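Nuclear RNA was sequenced from HEC-1-A cells, a line established from a human endometrial adenocarcinoma, in 2 control libraries and 2 libraries labelled METTL3 knockdown. METTL3 is the catalytic subunit of the complex that writes N6-methyladenosine (m6A) onto RNA, and the design asks how gene expression differs between the groups. The counts on annotated genes were 31574616 and 43989871 in control replicates 1 and 2, and 28296403 and 30103364 in the libraries labelled METTL3 knockdown. ERCC spike-in transcripts, synthetic RNAs added in a fixed volume to each sample, held 27895 and 37846 counts in the controls and 19339 and 21291 in the labelled knockdown libraries. Values are library-size-scaled counts after TMM normalisation (CPM), as mean ± SD with n = 2, and fold changes are the libraries labelled METTL3 knockdown over control. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

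METTL3 RNA (ENSG00000165819.11; hg38 chromosome 14, 21498133 to 21511375, minus strand) was not lower in the libraries labelled METTL3 knockdown. It stood at 51.3 and 51.5 CPM in the controls and at 49.6 and 49.5 CPM in the labelled knockdown libraries, or 51.4 ± 0.145 against 49.6 ± 0.0426 CPM (SD, n = 2). The log2 fold change was -0.05 (SE 0.06), with an adjusted p of 0.585 in edgeR's quasi-likelihood test and 95% bounds of -0.18 and 0.08, so that the largest reduction this interval allows was 12%. Scaled to the spike-ins it was 0.37, with an adjusted p of 4.6e-05 in that test, and scaled to library size alone 0.04. The spike-in scaling moved log2 fold changes by 0.42 at the median, so 0.37 reflects that shift of all genes and not a rise of METTL3 itself. The target gene therefore goes against the label of these libraries, and every direction given here is that of libraries labelled METTL3 knockdown against control. The method of knockdown is not given in the sources used here, and METTL3 protein, cytoplasmic METTL3 mRNA and m6A were not analysed here.

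The composition of the libraries also differed with the group. Reads outside annotated exons, which in nuclear RNA include introns, made up 47.8% ± 0.0253 of reported reads in the controls and 54.8% ± 0.00962 in the libraries labelled METTL3 knockdown (SD, n = 2). Mitochondrial genes held 2.36% ± 0.0300 of gene counts in the controls and 1.40% ± 0.00931 in the labelled knockdown libraries. Gene counts per spike-in count rose from 1147 ± 21.5 to 1439 ± 34.8, a ratio of 1.25, whereas mitochondrial counts per spike-in count went from 27.1 ± 0.853 to 20.1 ± 0.621. Each of these differences exceeded the spread between replicates, but 2 against 2 samples allow no two-sided exact permutation p below 0.333, which each of them reached. Scaling to the spike-ins added 0.42 to the median log2 fold change of all genes, so the values in the following paragraphs are changes relative to the other genes unless the spike-in scaling is named.

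**Figure D1:**
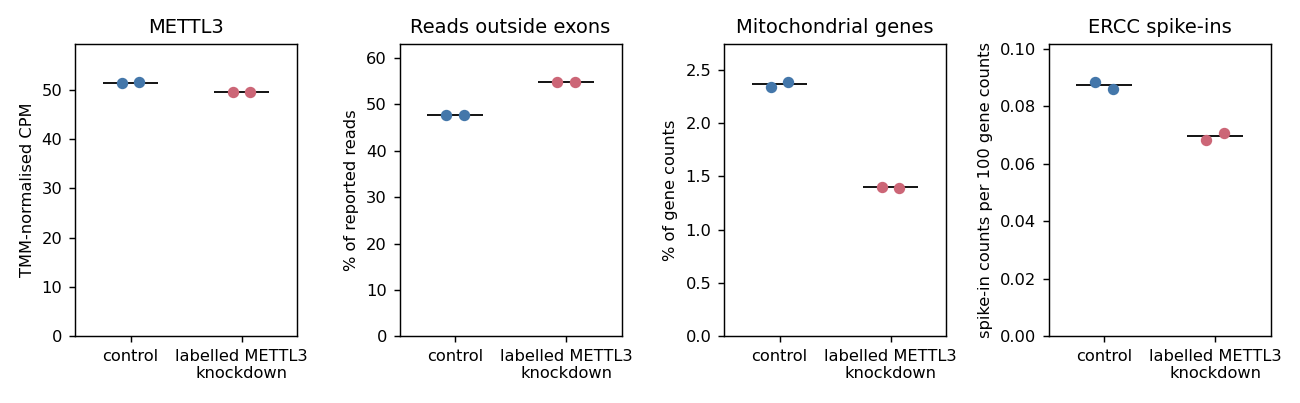
Each panel plots a measure per library (points) and its group mean (bar): METTL3 in TMM-normalised CPM, reads outside exons as a percentage of reported reads, mitochondrial genes as a percentage of gene counts, and ERCC spike-in counts per 100 gene counts. METTL3 lies near 50 CPM in all 4 libraries, while reads outside exons average 47.8% in control and 54.8% in the libraries labelled METTL3 knockdown.

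Of the genes that differed, several adhesion molecules and BDNF were among the most increased, and tenascin C and the kinase STK32A the most reduced. PCDH7, a protocadherin, rose 12.6-fold, from 1.25 ± 0.328 to 16.2 ± 0.118 CPM (SD, n = 2), in the libraries labelled METTL3 knockdown, and BDNF, a neurotrophin, 6.81-fold, from 5.74 ± 0.596 to 39.4 ± 0.642 CPM. Rises between 5.46-fold and 6.20-fold were seen for ALDH3A1 (an aldehyde dehydrogenase), CDH2 (N-cadherin), L1CAM (an adhesion molecule of the immunoglobulin superfamily), TRIM29, ENC1, KRT13 (a keratin of stratified epithelia) and NEBL (an actin-binding protein). In the other direction, TNC, an extracellular matrix glycoprotein (ENSG00000041982.15; chromosome 9, 115019578 to 115118257), fell from 1338 ± 19.1 to 46.7 ± 1.64 CPM, a log2 fold change of -4.84 (SE 0.04). STK32A (ENSG00000169302.15; chromosome 5, 147234963 to 147387852) fell from 43.3 ± 4.09 to 0.509 ± 0.237 CPM, and LCP1, an actin-bundling protein, from 219 ± 0.527 to 15.4 ± 2.1 CPM. SIGLEC15, TRPS1, CD24, the chemokine receptor CXCR4, KHDRBS3, SCEL and the kinase scaffold AKAP12 fell between 7.04-fold and 15.7-fold. The largest adjusted p among these genes was 1.9e-12, for ALDH3A1, in edgeR's quasi-likelihood test, and all of them moved the same way with the spike-in scaling.

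Altogether 7257 of 22029 tested genes (32.9%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3255 of them higher and 4002 lower in the libraries labelled METTL3 knockdown. A change of at least 2-fold was fitted for 1303 of them, 852 higher and 451 lower. The balance of directions depended on the scaling. With spike-in totals as library sizes 11775 genes passed, 11017 higher and 758 lower, so that 93.6% of the called genes were higher against 44.9% in the main test, and with library size alone 7415 passed, 61.9% of them higher.

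**Figure D2:**
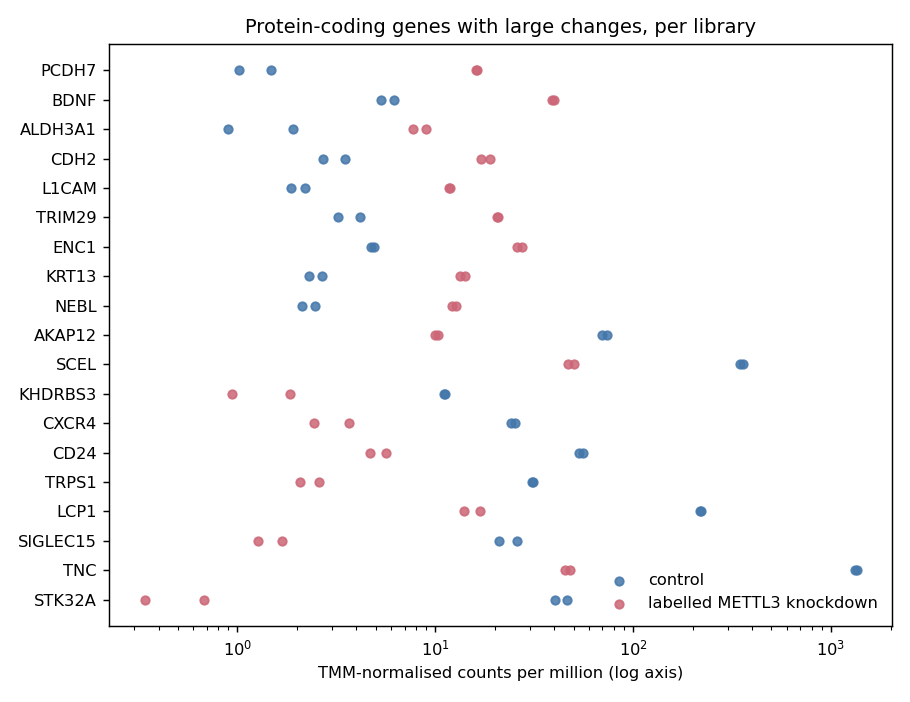
TMM-normalised CPM (log axis) of the protein-coding genes named for their large rises and falls, in each control library and each library labelled METTL3 knockdown (points). By the naming rule the libraries of the groups do not overlap for any of these genes, as is so for 63.8% of all tested genes. TNC goes from a mean of 1338 to 46.7 CPM.

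Noncoding RNAs were among the changed genes. GAS6-AS1, antisense to GAS6, rose 9.94-fold, from 1.52 ± 0.0527 to 15.1 ± 0.590 CPM (SD, n = 2), in the libraries labelled METTL3 knockdown, MIR100HG, a microRNA host transcript, rose 3.56-fold and ADIRF-AS1 2.79-fold. SH3TC2-DT fell from 49.1 ± 1.00 to 9.20 ± 1.30 CPM, and VLDLR-AS1 and LINC01629 fell 4.06-fold and 3.85-fold. All 6 kept their direction with the spike-in scaling. The lncRNA MALAT1 of nuclear speckles alone took 2.27% ± 0.00953 of gene counts in control and 3.19% ± 0.0529 in the labelled knockdown libraries. It rose 1.31-fold, and KCNQ1OT1, the antisense transcript of the imprinted KCNQ1 locus, rose 1.79-fold from 221 ± 4.38 to 396 ± 6.40 CPM. NEAT1, the scaffold of paraspeckles, fell to 0.791 of control, but stood at 0.08 on the log2 scale with the spike-in scaling. The list of nuclear and other noncoding RNAs that holds these genes did not move as a whole: of 29 measured members 9 rose and 6 fell (10 and 7 adjusted over the list alone), with a median log2 fold change of 0.02 and an adjusted p of 0.249 in camera, although 25 were higher and 1 lower with the spike-in scaling. That list also holds RN7SL2, the cytoplasmic 7SL RNA of the signal recognition particle, which fell from 2370 ± 56.3 to 1136 ± 37.6 CPM.

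By annotation class, sense-intronic transcripts, which lie within introns of a host gene on its strand, stood higher in the libraries labelled METTL3 knockdown. Of 495 tested, 78 rose and 5 fell (54 and 1 adjusted over the list alone), with a median log2 fold change of 0.37 and an adjusted p of 0.0423 in camera over 18 classes. The adjusted p was 0.0924 with an estimated correlation. Intronic processed pseudogenes on the strand of their host held a median of 140 counts against 4 on the opposite strand, so such loci can hold host reads. Reads outside exons were also higher in these libraries. A rise of sense-intronic transcripts therefore cannot be told apart from more intronic reads of their hosts. Protein-coding genes stood lower, with 2310 higher and 3611 lower of 14263 (2400 and 3739 adjusted over the list alone), a median of -0.04 but a mean of 0.01 and an adjusted p of 0.0423, or 0.0438 with an estimated correlation, whereas their median was 0.38 with the spike-in scaling. None of the other 16 classes passed. Long intergenic RNAs took 3.25% ± 0.0102 of gene counts in control and 4.29% ± 0.0490 in the labelled knockdown libraries, and most of that rise was MALAT1, which went from 2.27% to 3.19%. Small nucleolar RNAs took 0.438% ± 0.0386 and 0.360% ± 0.0105, although their median log2 fold change was 0.13, with 4 of 160 higher and 11 lower (2 and 10 adjusted over the list alone) and an adjusted p of 0.882.

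The lists that fell furthest were mRNAs of the cytoplasmic ribosome and of the mitochondrion. Of 76 ribosomal protein genes, 71 fell and none rose in the libraries labelled METTL3 knockdown, with the same count adjusted over the list alone. Their median log2 fold change was -0.62, and RPS6 went from 526 ± 0.852 to 254 ± 8.08 CPM and RPL13A from 1073 ± 6.09 to 591 ± 4.47 CPM (SD, n = 2). The adjusted p in camera was 6.5e-87, and this was the 1 list of 26 that also passed with an estimated correlation (adjusted p = 0.0371). With the spike-in scaling the median was -0.20, with 52 genes lower and 2 higher. All 13 mRNAs encoded by mitochondrial DNA fell, also adjusted over the list alone, with a median of -0.72 and -0.30 with the spike-in scaling, where 12 were lower and 1 was higher. MT-CO1, a subunit of cytochrome c oxidase, went from 7859 ± 96.5 to 4099 ± 5.70 CPM, and MT-CO3 from 3242 ± 55.7 to 1394 ± 12.6 CPM. Camera gave an adjusted p of 7.2e-43, and 0.139 with an estimated correlation. Among nuclear genes of oxidative phosphorylation 24 of 39 fell and none rose (25 and 0 adjusted over the list alone), with a median of -0.24, led by COX5B, from 108 ± 7.94 to 58.5 ± 0.803 CPM. For this list the adjusted p was 1.8e-05, and 0.139 with an estimated correlation, and with the spike-in scaling its median was 0.18. These lists moved together with RN7SL2, whose log2 fold change was -1.06 (SE 0.03), and with the lower mitochondrial share of the same libraries. Ribosomal protein, 7SL and mitochondrial genes have near-identical copies elsewhere in the genome, so their counts are uncertain.

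**Figure D3:**
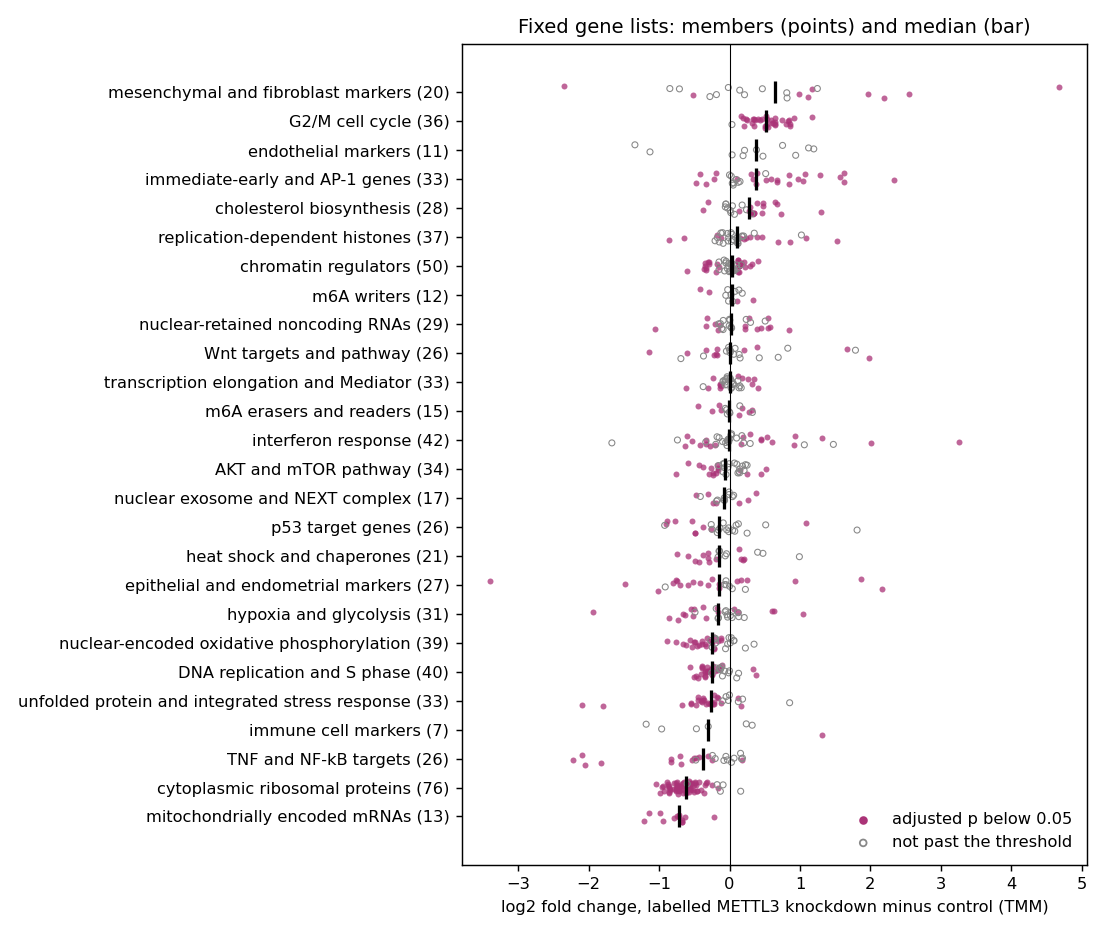
Log2 fold changes, libraries labelled METTL3 knockdown minus control after TMM scaling, of the measured members of each of the 26 lists (points, filled where the adjusted p is below 0.05) and the list median (bar), with the number of members in brackets. G2/M genes lie above 0, mitochondrially encoded mRNAs below 0 and ribosomal protein mRNAs below 0 except RPL22, at 0.16. With the spike-in scaling the ribosomal protein and mitochondrial medians stay below 0, at -0.20 and -0.30, and the medians of the other lists drawn below 0 lie above it.

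Genes of mitosis rose and genes of DNA replication fell relative to other genes. Of 36 G2/M genes 35 rose and none fell in the libraries labelled METTL3 knockdown, with the same count adjusted over the list alone, and BUB3 alone did not pass. The median log2 fold change was 0.52. The mitotic kinesin KIF20A went from 103 ± 2.51 to 233 ± 7.47 CPM (SD, n = 2), CENPF, a kinetochore protein, from 661 ± 21.5 to 1190 ± 16.6, TOP2A, which untangles DNA, from 982 ± 9.90 to 1653 ± 25.4, and the proliferation marker MKI67 from 1098 ± 5.37 to 1657 ± 3.35. Camera gave an adjusted p of 2.8e-35, and 0.139 with an estimated correlation. Of 40 replication and S-phase genes 26 fell, and RRM2 and TYMS, which make deoxynucleotides, rose (27 and 3 adjusted over the list alone). The median was -0.25, with MCM2, a subunit of the replicative helicase, going from 423 ± 1.63 to 322 ± 10.3 CPM and DNA ligase LIG1 from 277 ± 3.15 to 212 ± 4.38. This list had an adjusted p of 1.8e-05, and 0.139 with an estimated correlation, and its median was 0.17 with the spike-in scaling, where no member was lower. Replication-dependent histone genes were mixed, with 10 of 37 higher and HIST2H3D, HIST1H3A, HIST1H2AE and HIST1H1C lower, the same counts adjusted over the list alone, a median of 0.11 and an adjusted p of 0.458, although 31 were higher and 1 lower with the spike-in scaling. Histone copies are near-identical, so their counts are uncertain.

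Immediate-early genes, which growth factors and stress induce within minutes, stood higher in the libraries labelled METTL3 knockdown. Of 33 measured, 19 rose and FOSL2, IER3, DUSP5, MYC and KLF6 fell (20 and 5 adjusted over the list alone), with a median log2 fold change of 0.38. EGR1 went from 253 ± 0.0784 to 532 ± 9.45 CPM (SD, n = 2), FOS from 127 ± 3.27 to 228 ± 2.06, CYR61, a secreted matricellular protein, from 36.3 ± 1.38 to 108 ± 6.58, and the MAP kinase phosphatase DUSP4 from 13.8 ± 0.618 to 42.2 ± 3.86. Its adjusted p was 3.3e-12, and 0.139 with an estimated correlation. Genes of cholesterol synthesis and uptake also stood higher, with 15 of 28 risen and TM7SF2 and PMVK fallen (16 and 2 adjusted over the list alone) and a median of 0.28. SCD, a fatty acid desaturase, rose 1.60-fold, HMGCS1 1.66-fold and FDPS 1.38-fold. Here the adjusted p was 3.5e-07, and 0.139 with an estimated correlation.

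Stress response lists stood lower relative to all tested genes, noncoding ones included. They were not compared with matched protein-coding genes. Draws matched to the ribosomal protein, G2/M and S-phase lists had mean medians of -0.18, -0.13 and -0.13. The chaperone and hypoxia medians below lay near these values, and whether those lists fell more than similar coding genes was not tested. In the unfolded protein and integrated stress response 24 of 33 genes fell and PPP1R15A and PSAT1 rose in the libraries labelled METTL3 knockdown, the same counts adjusted over the list alone, with a median log2 fold change of -0.26. VLDLR, a lipoprotein receptor, went from 138 ± 3.89 to 39.6 ± 2.11 CPM (SD, n = 2), EDEM1, which acts in degradation of misfolded glycoproteins, from 271 ± 8.65 to 170 ± 3.92, the mitochondrial enzyme SHMT2 from 341 ± 4.64 to 234 ± 4.44, and the cystine transporter SLC7A11 from 715 ± 21.8 to 513 ± 14.8. Its adjusted p was 2.5e-10, and 0.139 with an estimated correlation, and the median was 0.16 with the spike-in scaling. Of 21 chaperone genes 9 fell and DNAJB6, CHORDC1, DNAJB4 and DNAJB1 rose, also adjusted over the list alone, with a median of -0.15, and HSP90AA1 went from 2165 ± 4.80 to 1293 ± 41.7 CPM and HSPA8 from 2197 ± 6.01 to 1570 ± 11.8. For chaperones the adjusted p was 0.0086, and 0.187 with an estimated correlation, and the median was 0.27 with the spike-in scaling. Of 26 targets of TNF and NF-kB 14 fell and LIF rose, the same adjusted over the list alone, with a median of -0.37. The inhibitor NFKBIA went from 76.5 ± 2.39 to 47.6 ± 0.780 CPM and BIRC3, an inhibitor of apoptosis, from 27.8 ± 0.661 to 15.6 ± 0.0458. This list had an adjusted p of 0.0062, and 0.185 with an estimated correlation, and its median was 0.05 with the spike-in scaling, where 7 were higher and 7 lower. Of 31 genes of hypoxia and glycolysis 12 fell and PKM, KDM3A, ALDOA, SLC2A1 and ALDOC rose (14 and 6 adjusted over the list alone), with a median of -0.16. NDRG1, a hypoxia-induced gene, fell 3.83-fold from 148 ± 0.833 to 38.6 ± 1.27 CPM, VEGFA 1.81-fold and the glycolytic enzyme GAPDH 1.55-fold. The adjusted p was 1.1e-04, and 0.139 with an estimated correlation, and the median was 0.27 with the spike-in scaling.

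Epithelial markers stood lower and mesenchymal markers higher in the libraries labelled METTL3 knockdown, with members going both ways in each list. The epithelial list was not compared with matched protein-coding genes, and draws matched to other lists had mean medians of -0.13 to -0.18. Of 27 epithelial and endometrial markers 14 fell and 6 rose, the same counts adjusted over the list alone, with a median log2 fold change of -0.15. CD24, a surface glycoprotein, went from 54.5 ± 1.64 to 5.16 ± 0.675 CPM (SD, n = 2), PAX8, a transcription factor of the Müllerian epithelium, from 790 ± 8.91 to 393 ± 6.77, desmoplakin DSP from 1182 ± 12.7 to 704 ± 2.07 and the tight junction protein CLDN4 from 641 ± 15.3 to 394 ± 11.1. Camera gave them an adjusted p of 7.1e-08, and 0.139 with an estimated correlation, and the median was 0.27 with the spike-in scaling. Of 20 mesenchymal and fibroblast markers 7 rose and FAP and S100A4 fell, also adjusted over the list alone, with a median of 0.64. Fibronectin FN1 rose 4.59-fold from 7.18 ± 0.0693 to 32.9 ± 3.52 CPM, CDH2 5.86-fold, and the repressor of E-cadherin ZEB1 2.26-fold, and vimentin VIM went from 0.103 ± 0.0534 CPM, close to the detection limit, to 2.87 ± 0.0503. Camera gave this list an adjusted p of 0.01, and 0.187 with an estimated correlation. None of 11 endothelial markers passed, also adjusted over the list alone, with a median of 0.38 and an adjusted p of 0.758; ROBO4 stood at 1.53 ± 0.398 and 2.61 ± 0.0862 CPM. Of 7 measured immune cell markers CD8A rose from 0.928 ± 0.0813 to 2.29 ± 0.0494 CPM and none fell, also adjusted over the list alone. The adjusted p was 0.951, with a median of -0.30 and a mean of -0.15 although the test leaned upward.

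The machinery of m6A changed little as a group. Of 12 writer genes VIRMA, a scaffold of the methyltransferase complex, and RBM15 rose, RBM15B and METTL5 fell in the libraries labelled METTL3 knockdown, the same adjusted over the list alone, and METTL3 with 7 others did not pass. VIRMA went from 110 ± 3.09 to 139 ± 3.11 CPM (SD, n = 2) and RBM15B from 102 ± 5.79 to 76.7 ± 1.70, with a list median log2 fold change of 0.03 and an adjusted p of 0.819. RBM15B and METTL5 stood at 0.00 and 0.13 with the spike-in scaling, and the calls of RBM15 and METTL5 were lost without single libraries. Without control replicate 1 and without either labelled knockdown library RBM15 had adjusted p of 0.284, 0.201 and 0.0643, and METTL5 0.279 without control replicate 2 and 0.194 without labelled knockdown replicate 2. Of 15 erasers and readers FTO, YTHDF2, IGF2BP3 and HNRNPA2B1 rose and ALKBH5, IGF2BP2, PRRC2A and RBMX fell, the same adjusted over the list alone. The demethylase ALKBH5 went from 69.7 ± 2.23 to 51.4 ± 0.705 CPM and the reader HNRNPA2B1 from 860 ± 21.6 to 1072 ± 30. In an upward test the adjusted p was 0.864, with a median of -0.00 and a mean of 0.02. The nuclear exosome and NEXT complex, which degrade nuclear RNA, had RBM7, EXOSC6 and EXOSC2 higher and EXOSC5, EXOSC8, EXOSC10 and DIS3 lower of 17 (3 and 5 adjusted over the list alone), a median of -0.08 and an adjusted p of 0.709. Of 33 elongation and Mediator genes 6 rose and 7 fell, the same adjusted over the list alone, among them POLR2A, the largest subunit of RNA polymerase II, from 162 ± 0.994 to 214 ± 1.92 CPM. For this list the adjusted p was 0.819, with a median of 0.01 and a mean of -0.00. Of 50 chromatin regulators 16 rose and 12 fell (16 and 14 adjusted over the list alone), with the remodeller CHD7 from 412 ± 5.41 to 323 ± 3.33 CPM and the methyltransferase KMT2A from 607 ± 12.2 to 489 ± 5.83. Both stood above 0 with the spike-in scaling, at 0.07 and 0.11. The adjusted p was 0.958, with a median of 0.03 and a mean of -0.01. These balances rest on the scaling: with spike-in totals as library sizes 10 writers were higher and none lower, 14 and none of the erasers and readers, 12 and none of the exosome, 31 and none of the elongation and Mediator genes, and 42 and 1 of the chromatin regulators.

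Other signalling lists did not pass. Of 26 p53 targets 8 fell and PLK2 rose in the libraries labelled METTL3 knockdown, also adjusted over the list alone, with a median log2 fold change of -0.15 and an adjusted p of 0.249. PLK2, a polo-like kinase, went from 150 ± 3.03 to 319 ± 4.94 CPM (SD, n = 2) and the cytokine GDF15 from 182 ± 6.62 to 97.6 ± 3.99. Of 34 genes of the AKT and mTOR pathway 12 fell and PHLPP1, TSC1, PIK3CB and PHLPP2 rose (14 and 4 adjusted over the list alone), with a median of -0.06 and an adjusted p of 0.417. EIF4EBP1, a repressor of translation, went from 99.3 ± 0.622 to 58.5 ± 3.0 CPM. Of 26 Wnt genes 7 fell and CTNNB1, CCND1, BMP4 and WNT10A rose (8 and 5 adjusted over the list alone), with an adjusted p of 0.845 in a downward test, a median of 0.01 and a mean of 0.17. WNT7A went from 69.2 ± 3.22 to 31.4 ± 0.958 CPM and WNT10A from 2.35 ± 0.202 to 9.23 ± 0.740. Of 42 interferon response genes 12 rose and 8 fell (12 and 9 adjusted over the list alone), with an adjusted p of 0.859 in an upward test, a median of -0.00 and a mean of 0.18. SAMD9 went from 26.0 ± 1.33 to 49.7 ± 0.469 CPM and B2M, the light chain of MHC class I, from 309 ± 10.6 to 204 ± 4.85. With the spike-in scaling the balance of these lists turned upward, with 14 p53 targets higher and 2 lower, 26 and 1 of the AKT and mTOR genes, 18 and 2 of the Wnt genes and 26 and 2 of the interferon response genes.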

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

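The tests on 7SL RNA, on the mitochondrially encoded mRNAs and on intron length were chosen only after the results they bear on were seen.

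Reads outside annotated exons stand apart from the counted genes, and they were raised in the libraries labelled METTL3 knockdown, at 54.8% ± 0.00962 of reported reads against 47.8% ± 0.0253 in control (SD, n = 2). Per spike-in count they went from 1213 ± 28.2 to 2028 ± 50.9, a ratio of 1.67, with an exact permutation p of 0.333, the smallest that 2 against 2 samples allow. The lower ribosomal protein and mitochondrially encoded mRNAs came from the same libraries, and the 2 observations are weighed together.

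The tables argue against a bias of length, GC content, intron length or expression level as the whole cause in the ribosomal protein genes, since their median log2 fold change of -0.62 lay below all 1000 draws of matched genes, whose medians averaged -0.18 and were at lowest -0.32. How close the matched genes were on these measures was not checked, so a bias that the match did not cover stays open. Loss of mitochondria from the nuclear fraction as the whole cause of the lower mitochondrially encoded mRNAs would lower them by 1 shared factor, but they fell by between 0.23 and 1.22 on the log2 scale, with a chi-square per degree of freedom of 64.3 against their SEs. Those SEs rest on replicates that may be technical, and near-identical copies elsewhere in the genome make these counts uncertain. The spread argues against a shared factor only as far as the counts hold. Less cytoplasmic carry-over stays open for the ribosomal protein mRNAs, since cytoplasmic RN7SL2 also changed, with a log2 fold change of -1.06, although 7SL copies share reads. More unspliced RNA stays open as well, since the quintile of expressed genes with the longest introns had a median log2 fold change 0.15 above the quintile with the shortest, ribosomal protein genes left out. Neither carry-over nor splicing was measured, whether a fixed mass of RNA was used is not given, and an effect of METTL3 stays open and untested.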

How the results depend on the processing

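No alternative was added later. Changed genes numbered 6661 with DESeq2, 7211 with limma-voom, 7283 with median-of-ratios factors, 6739 without a filter, 7278 with the stricter filter, 7240 without mitochondrial, rRNA, 7SK and 7SL genes, 8465 at an adjusted p of 0.1, and 6018 to 6105 when each library was left out in turn, against 7257. The series table equals the library tables, so it gave no separate value. Replicate numbers did not pair the samples: the differences between replicates 1 and 2 in the groups correlated with r = -0.03 across 11697 genes, which are not independent, and a replicate block gave 7208 changed genes and changed no call of a named gene, list or class. Fewer genes passed with a change of at least 1.5-fold, 2654 (1571 higher, 1083 lower), as that rule demands more.

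Spike-in totals as library sizes gave 11775 changed genes (11017 higher, 758 lower), since they shift all log2 fold changes by about 0.42, and 4013 of the 5054 genes called both ways kept their direction. METTL3 then stood at 0.37, and at 0.043 with library size alone. For the same reason genes slightly below 0 came to stand above it: SESN2 at 0.045, CHD7 0.073, KMT2A 0.11, SMARCA2 0.076, BRD2 0.054, MCM2 0.028, MCM7 0.076, MCM4 0.077, LIG1 0.036, HSP90AB1 0.12, DTX3L 0.0091, IGF2BP2 0.17, RBM15B 0.0021, METTL5 0.13, EXOSC10 0.18, EXOSC8 0.12, NEAT1 0.084 and MED13L 0.11. So did the medians of AKT and mTOR (0.36), S phase (0.17), epithelial (0.27), heat shock (0.27), hypoxia (0.27), immune (0.11), interferon (0.42), m6A erasers and readers (0.42), exosome (0.35), oxidative phosphorylation (0.18), p53 (0.27), TNF and NF-kB (0.049) and unfolded protein (0.16) lists and of protein-coding genes (0.38). Whether input or RNA per cell sets this shift was not tested.

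Of the 26 lists 13 passed, 1 with an estimated correlation, 20 with fry and 23 with fry on the spike-in scale, and of the 18 classes 2 passed, against 1, 14 and 18, and 4 with the stricter filter. Fry asks whether a set moves at all, not whether it moves more than other genes. Leaving out single libraries kept 13 lists and 2 classes past the threshold. Lists and classes with medians near 0 turned sign: interferon was 0.0049 with the stricter filter and -0.034 to 0.021 over the libraries left out, m6A erasers and readers 0.015 with the stricter filter, writers -0.016 to 0.061 over the libraries left out, elongation and Mediator -0.013 to -0.0070, zinc finger genes -0.0013 to 0.016 and transcribed unitary pseudogenes -0.12 to 0.099. Each fit without a library filtered the genes anew, with 24078 to 24299 tested against 22029, so the measured members of a list can differ. The immune list was not near 0, at -0.30 over 7 genes, and turned to 0.0036 to 0.45 in all of these fits, while its member ITGAM, at -0.47, ranged from -0.82 to 0.0055. The cause was not tested, but none of these sets passed in any of those fits. The differences in spike-in ratio and mitochondrial share moved by less than the spread between replicates. At this depth genes below about 1 CPM, such as the endothelial and immune markers, have wide errors.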

Other observations

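The tests on METTL3 and on families of genes by symbol were chosen only after the results were seen, and those on neighbouring genes and on genes matched to the ribosomal protein list before. Draws matched to the G2/M and S-phase lists were not among the predictions written beforehand, and they were counted in the direction of each list alone.

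Grouping protein-coding genes by the letters that open their symbol gave 195 families, of which 10 passed camera with the preset correlation and none with an estimated correlation, where the smallest adjusted p was 0.444. The strongest were RPL and RPS, mostly ribosomal protein genes. RPL had 42 of 49 members lower and none higher, with an adjusted p of 7.8e-48. RPS, which by its letters also takes in the RPS6K kinases, had 33 of 42 lower and 3 higher, with 2.0e-33. Both lost their call at an estimated correlation (0.444), whereas the fixed list of ribosomal protein genes kept it (0.0371). The families were adjusted over 195 tests and the fixed lists over far fewer, so these adjusted p-values cannot be compared directly. Kinesins (KIF), motors of the spindle and of transport, had 17 of 37 members higher and 10 lower in the libraries labelled METTL3 knockdown, with a median log2 fold change of 0.30. The family shares members such as KIF20A with the G2/M list, so it partly repeats that result. Translation initiation factors (EIF) had 23 of 54 lower and 3 higher, with a median of -0.18 but 0.24 with the spike-in scaling. Elongation factors (EEF) had 6 of 12 lower and 2 higher, with a median of -0.31 and 0.12 with that scaling, and the TMED cargo receptors of the early secretory pathway 7 of 10 lower and none higher, at -0.28 and 0.14. Claudins (CLDN), the strand proteins of tight junctions, had 7 of 13 lower and 1 higher, with a median of -0.42 that was 0.00 with the spike-in scaling.

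The median of the G2/M genes, 0.52, lay above all 1000 draws of matched genes, whose medians averaged -0.13 and reached 0.00 at most. The median of the S-phase genes, -0.25, was reached by 3 of 1000 draws, whose medians averaged -0.13, so matched genes share part of that fall. The histone median of 0.11 had 95% bootstrap bounds of -0.01 and 0.18. These bounds came from resampling the 37 genes and not the libraries, so they describe the spread of members and not the error of the group difference.

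METTL3 was not lower in the libraries labelled METTL3 knockdown. The replicates argue against an exchange of 1 library in each group, since their largest chi-square per degree of freedom within a group was 4.75 against at least 54.3 between groups. This holds only if the treatment, and not a difference between cultures or sublines, separates the groups, which was not tested. Reads from the antisense neighbour are excluded as the main source of METTL3 counts, since pseudogenes opposite to their host had a median of 4 counts against 140 on its strand. An exchange of the labels of the groups cannot be told apart from the labels as given, since METTL3 was not clearly lower, with an upper 95% bound of 0.077 on its log2 fold change. Its value of 0.37 with the spike-in scaling does not bear on this, since that scaling moved all genes by 0.42 at the median. What also stays open, and was not tested, is a knockdown that had failed or ended by the time of harvest, one that acts on cytoplasmic mRNA or on protein and may leave nuclear RNA as it was, or another treatment than the label names.

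Neighbouring genes shifted together on chromosomes 9 and 21. Among windows of 50 neighbouring expressed genes, the largest median, relative to all such genes, was 0.38 on the log2 scale, on chromosome 9 between 87725519 and 98796965, where 47 of 50 genes lay above the median of all, and that of chromosome 21 was 0.287, between 37059170 and 46665124, with 44 of 50 genes above, against at most 0.279 in 1000 shuffled gene orders. The largest windows of chromosomes 11 and 19 went the other way, at -0.259 and -0.232, within the range of the shuffled orders. Shuffling does not keep traits that neighbours may share, such as intron length, along which fold changes also differed. The shuffled range may therefore be too narrow, and chromosome 21 passed it only slightly. Chromosome 9 as a whole had a median of 0.21 over 445 genes, and chromosome 21 of 0.25 over 97. A candidate explanation is a difference in copy number between the cultures behind the groups, which would make part of the changes a matter of subline rather than of METTL3. Copy number was not measured here, and regional control of transcription and an effect of METTL3 stay open.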
